A study of Mus musculus with 4 samples.

How the data were processed

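The series holds 4 arrays of mouse bone marrow cells, 1 each for KSL with GFP, KSL with Plzf, MP with GFP and MP with Plzf. Per the labels, cells were cultured with stem cell factor, thrombopoietin, interleukin 6 and FLT3 ligand, transduced with a retrovirus carrying Plzf and EGFP or EGFP alone, and sorted for GFP, and the RNA was amplified and labelled with Cy3. Per the file headers, Agilent Feature Extraction 10.7.1.1 read the arrays, whereas the submitters' processing notes give version 9.5.1.1. The deposited scanner tables hold the processed signal as linear intensity, background-subtracted and detrended, with no normalisation between arrays, and the mean and local background of each spot. The deposited series matrix holds linear intensity that was quantile normalised between the 4 arrays: every column has a median of 6.13 and an upper quartile of 71.9. Its log2 values correlated with the scanner values of their own array at r from 0.9995 to 0.9999, and at no more than 0.976 with another array. Its scale was therefore settled from the values.

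Control spots were left out, outlier spots were left out, and the spots of a probe were averaged, which kept 55678 probes and dropped 3. Genes were named through the probe's accession in the mouse RefSeq annotation for 27229 probes, 2837 of which had another name in the files, and 28449 kept the files' name. Probe positions are those of the files, on mm9. The log2 processed signal of each array was scaled by its 75th percentile. The plan said only the array's 75th percentile. It was taken over probes well above background on all 4 arrays, because most probes were not well above background. The 75th percentile over all probes, and scaling on 7 bright spike-in controls, were added as alternatives after the data had been seen. The 75th percentile of the signal over all probes was 99.0 on KSL GFP, 83.3 on KSL Plzf, 70.5 on MP GFP and 86.3 on MP Plzf. No spot was saturated. The median SD between replicate spots was 0.07 log2 on each array (0.0675 to 0.0742), and that between probes of a gene was 0.14 log2 for the Plzf difference in KSL and 0.21 in MP. Neither covers the spread between cultures.

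Groups were fixed from the labels before the data were examined, as were the comparisons, the alternatives, the 22 gene lists and the rule for named genes. A probe entered a comparison of 2 arrays if it was well above background on at least 1 of them. Where 1 side was not, the fold was taken against the higher of that array's lowest well-above-background signal and the probe's own signal, and is given as at least that fold. Probes were counted at 2-fold or more, with no test, since each group has 1 array. The test across populations was limma with Plzf and population as terms, on 20141 probes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, the difference of the Plzf effect between KSL and MP, beside 6.40 prior degrees of freedom, and uses the measured values also for probes not above background. All arrays are on 1 slide, so no slide block exists, and array position cannot be told apart from group.

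For gene lists the probe with the highest mean signal stood for each gene. The median log2 change of the members was placed among 10000 random lists of the same size, matched on mean level in 20 bins, as a description and not a test. Named genes were Zbtb16 and Eya2, the latter because of what is known of the study, then the 10 with the largest average Plzf difference in each direction among those at least 2-fold in both populations. They also include the 5 with the largest difference between populations in each direction, the 10 in each direction for MP over KSL with GFP, and up to 4 members per list (3 for MP over KSL). The fixed rule did not say how to rank bounds, so named genes were ranked only among genes well above background on the arrays compared. The genes of the added lists and those of the tests in the closing section were chosen after their values were seen. A list entry called Ifi27 is a probe the files call Ifi27l1, and Ly6c2 has no probe under its own name.

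The 7 added lists, chosen after the data were seen, hold tissue macrophage, stefin and neutrophil granule, antigen presentation, globin and haem, interferon, guanylate-binding and immunity-related GTPase, and inflammatory cytokine and chemokine genes. Alternatives were normexp background correction with an offset of 50, quantile normalisation, median centring, the deposited normalised values, no filter on dim probes, only probes well above background on all arrays compared, 1 probe or the mean of the probes per gene, thresholds of 1.5-fold and 3-fold, limma with a trend or robust prior, and an adjusted p of 0.1. The methods were tested on simulated data. In limma 16 of 50 probes with a log2 change of 2 were recovered and 50 of 50 with a change of 4, with 16 false calls among 20141 probes. That simulation drew the spread of each probe from limma's own fitted prior, with noise independent between probes. It therefore does not show how many of the real limma calls are false. The 2-fold count recovered 200 of 200 with 0 false calls, on 1 pair of arrays simulated from the KSL GFP array alone. Such a pair holds no spread between cultures, so it does not show how many of the real 2-fold probes are false. Of 100 random lists 5 fell outside the central 95%, and 10 of 10 shifted lists lay above it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.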

Results

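Gene expression was measured in hematopoietic stem and progenitor cells from the bone marrow of C57BL/6 mice after retroviral transfer of Plzf (gene symbol Zbtb16), a BTB zinc finger transcription factor, or of the vector with EGFP alone. Cells positive for GFP were sorted 48 hours after transduction, and their RNA was hybridised to Agilent single-colour arrays. Of the 4 arrays, 1 was KSL cells with GFP, 1 was KSL cells with Plzf, 1 was MP cells with GFP and 1 was MP cells with Plzf. KSL is in common use for c-Kit positive, Sca-1 positive, lineage negative cells, which are enriched for stem cells, and the labels do not spell out MP. The study looked for Plzf targets with a part in immortalization. There were no replicates, so no difference within a population could be set against the spread between cultures, and the small number of arrays limits the precision of every value. Of 55678 probes, 34.2% were well above background on the KSL GFP array, 35.2% on KSL Plzf, 34.4% on MP GFP and 36.2% on MP Plzf, and 16434 were so on all 4 arrays.

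The transferred gene itself could not be followed on the arrays. Its only probe, on mm9 chromosome 9 from 48462419 to 48462478 on the minus strand, gave signals of 5.0 and 7.40 on the KSL GFP and Plzf arrays and of 6.01 and 16.0 on the MP GFP and Plzf arrays, none of them well above background. These Zbtb16 signals therefore tell nothing about which cells carried Plzf. Eya2, a transcriptional coactivator of the Eya family, was higher with Plzf in both populations. It was singled out before the data were examined, because of what is known of the study that made these arrays. Its difference may therefore repeat what that study saw in them, and is no independent evidence. Its probe lies on mm9 chromosome 2 from 165597072 to 165597131 on the plus strand. Eya2 signal was 41.3 with GFP and 364 with Plzf in KSL cells, a 13.9-fold difference after scaling. In MP cells Eya2 was not above background with GFP and had a signal of 153 with Plzf, at least 10.3-fold higher. Across both populations the Eya2 difference was a log2 change of 3.81 ± 0.38 (SE from limma, 1 array per group), with a limma adjusted p of 0.00321, and it was higher with Plzf in both pairs of arrays. That Eya2 estimate, its SE and its adjusted p use the MP GFP signal as measured, below background, so the estimate is no bound. With the MP difference at its bound the mean is 3.58. The SE rests mostly on the prior drawn from all probes, with 6.40 prior degrees of freedom beside 1 residual. It does not measure the spread of Eya2 between cultures.

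The comparison of Plzf with GFP asked which genes differed after the transfer, first in each population and then in both. The genes with the largest average difference upward in both were Oasl1, an antiviral gene induced by interferon (65.3-fold in KSL and 228-fold in MP), the beta globin gene Hbb-bt (77.0-fold and 186-fold) and Stfa3, a stefin, which is a cysteine protease inhibitor of myeloid cells (512-fold and 26.6-fold). Next came Phf11a, the survival gene Bcl2a1d, Stfa2, Phf11d, the interferon-induced genes Oasl2 and Isg15, and Acod1, which makes itaconate in activated macrophages. The genes with the largest average difference downward were Muc13, a mucin (13.3-fold in KSL and 16.1-fold in MP), the potassium channel gene Kcnk12 (7.65-fold and 24.0-fold) and Prss57, a neutrophil serine protease (9.08-fold and 18.2-fold). Next came Trem3, Cldn15, Prss16, Ctsg, Mrgpra2a, Elane and Gfi1. All 20 passed limma, with adjusted p from 0.00129 for Hbb-bt to 0.0188 for Mrgpra2a. They were picked for a large average difference shared by both populations, which is what limma tests on the same arrays. Their passing was therefore largely set by the choice and is no separate evidence. With quantile normalisation or the deposited values none of them passed. The Phf11, stefin, Hbb and Mrgpra2 families hold close paralogs whose transcripts a probe can share.

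In KSL cells 3360 of 20637 probes were at least 2-fold apart, 2862 higher and 498 lower with Plzf. In MP cells it was 6089 of 21521, with 3986 higher and 2103 lower. At least 2-fold in the same direction in both populations were 1724 of 19032 probes, 1481 higher and 243 lower, where independent lists would share 410 and 45.0, given 2490 higher in KSL and 3137 in MP, and 439 and 1952 lower, among those 19032. Across 16434 probes the log2 differences in KSL and MP correlated with a Pearson r of 0.579 and a Spearman rho of 0.483, where genes are not independent replicates. The balance of higher and lower depended on the scaling. With quantile normalisation KSL had 1389 higher and 1095 lower, MP had 3200 higher and 3329 lower, and both had 800 higher and 500 lower. With spike-in scaling KSL had 954 higher and 4160 lower, MP had 4192 higher and 1944 lower, and both had 621 higher and 969 lower. The median log2 change of the probes was 0.20 in KSL and 0.00 in MP with the 75th percentile scaling, -0.05 and -0.15 with quantile normalisation and -0.53 and 0.04 with spike-in scaling, so a group median is better set against random lists of the same level than against 0. Of 22 gene lists, 10 medians lay above the central 95% of their random lists and 2 below in KSL, and 9 above and 4 below in MP. Those of Hox and self-renewal, lymphoid, cyclin D and CDK inhibitor, chromatin regulator, BTB zinc finger, stromal and endothelial, and reference genes lay within it in both populations, those of mitosis, p53 target and apoptosis, and cytokine signalling target genes in KSL, and those of Eya-Six-Dach network and Myc target genes in MP. These positions are those of the 75th percentile scaling. In KSL, Hox and self-renewal genes lay below the central 95% with quantile normalisation, the deposited values and the mean over probes. Mitosis genes lay below it in KSL with normexp. Cytokine signalling target genes lay above it in KSL over members well above background on all 4 arrays.

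**Figure D1:**
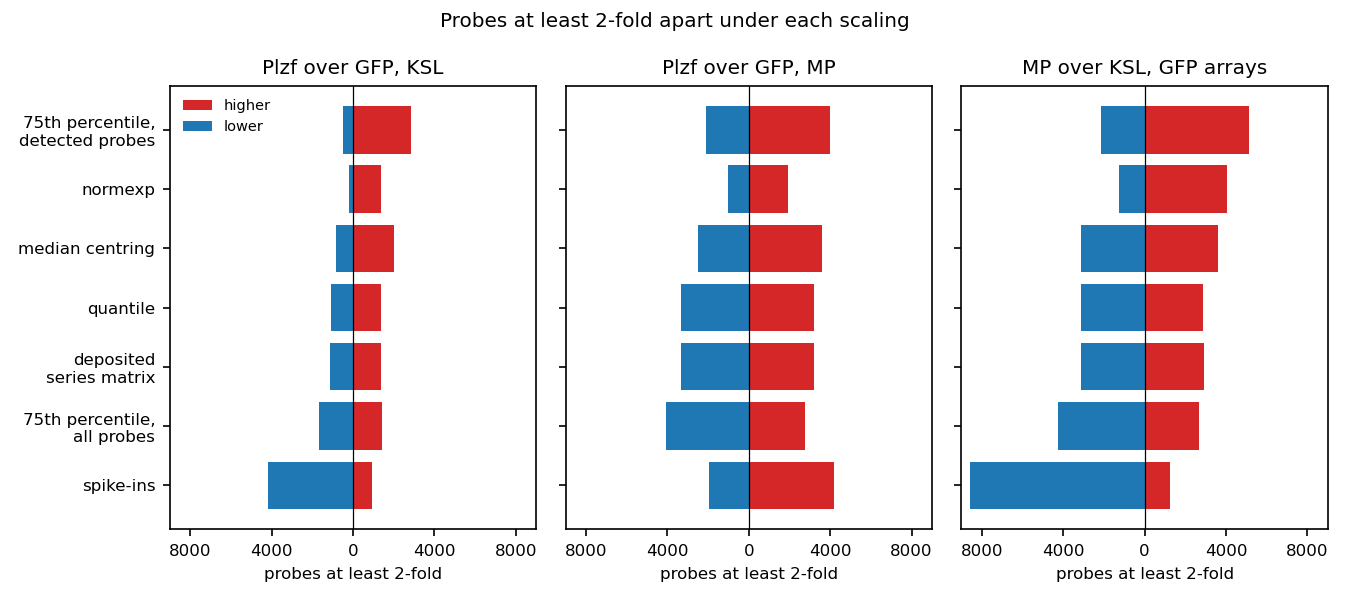
Probes at least 2-fold higher (red, to the right) or lower (blue, to the left) in 3 comparisons of single arrays, for each scaling of the arrays. In KSL cells 2862 were higher and 498 lower with the 75th percentile scaling of detected probes, against 954 higher and 4160 lower with the spike-in scaling.

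The test over all 4 arrays asked whether the average Plzf difference was large beside its disagreement between KSL and MP. It is no test against replicate cultures. With limma, 1200 of 20141 probes passed at an adjusted p under 0.05, 1047 of them higher and 153 lower with Plzf. Under quantile normalisation limma called 0 probes, with a smallest adjusted p of 0.0620 and 3265 probes at an unadjusted p under 0.05, against 3893 before. With the deposited normalised values it called 0 as well, with a smallest adjusted p of 0.0593 and 3293 at an unadjusted p under 0.05. The limma calls given for genes and lists are those of the 75th percentile scaling, and none of those over all probes passed with either of these.

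**Figure D2:**
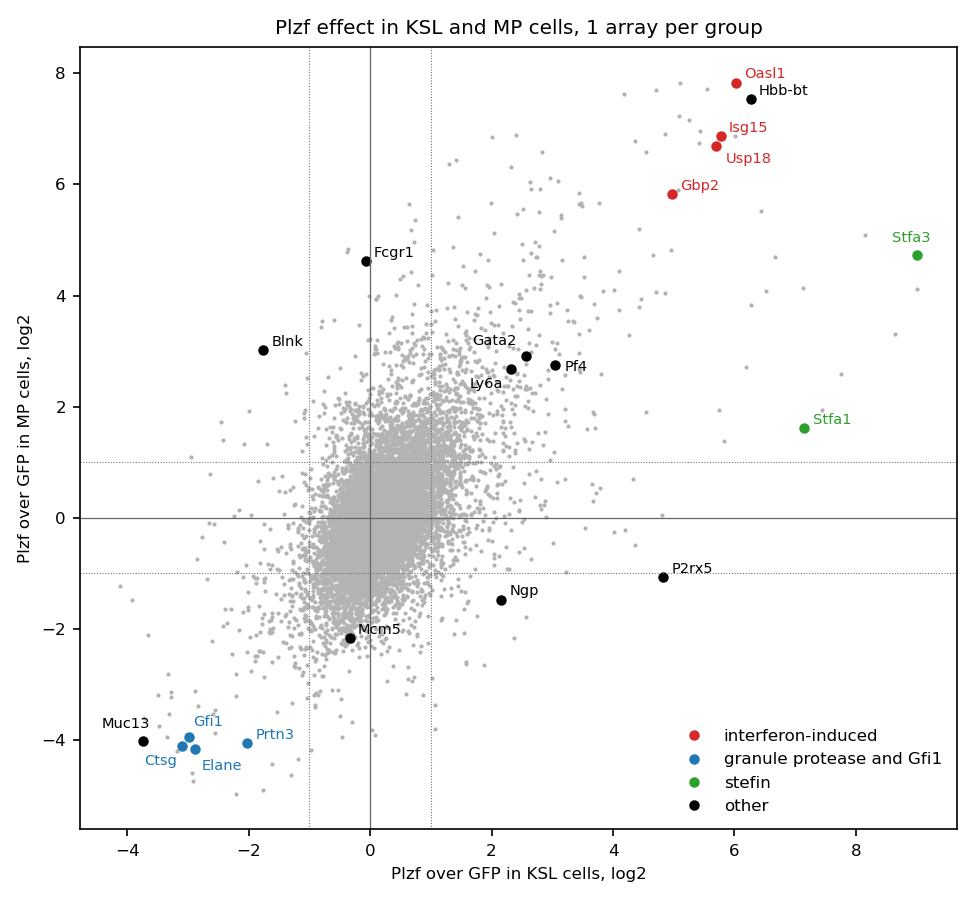
Log2 ratio of Plzf to GFP in KSL cells (horizontal) and in MP cells (vertical) for 12902 genes well above background on all 4 arrays, 1 array per group; dotted lines mark 2-fold. Oasl1, Isg15, Usp18 and Gbp2 lie at the upper right, Ctsg, Elane, Prtn3 and Gfi1 at the lower left, and Blnk and P2rx5 differ in sign between the populations.

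Interferon-stimulated genes were higher with Plzf as a group. All 18 measured members were at least 2-fold higher in KSL cells, with a median log2 change of 4.37, and 18 of 19 in MP cells, with a median of 6.41. Level-matched random lists had medians of 0.16 and -0.03, and no random list of 10000 came as high in either population. Isg15, a ubiquitin-like protein of the antiviral response, was 54.7-fold higher in KSL and 117-fold higher in MP, Usp18, which removes it, was 51.6-fold and 103-fold higher, and the GTPase gene Gbp2 was 31.5-fold and 56.5-fold higher. The exception was the Ifi27 probe, at log2 3.02 in KSL and -0.46 in MP. With limma 17 of 18 tested members passed over all probes, all higher, and 17 adjusted over the list alone. Tissue macrophage genes, a list chosen after the data were seen, were also higher, with medians of 1.53 in KSL and 4.63 in MP, or 0.83 and 1.28 over members well above background on all 4 arrays.

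Granulocyte genes did not move as a block. The proteases of primary granules were lower with Plzf in both populations: Ctsg by 8.56-fold in KSL and 17.2-fold in MP, Elane by 7.36-fold and 17.8-fold, and Prtn3 by 4.07-fold and 16.6-fold. Gfi1, a repressor needed for neutrophil development, was 7.90-fold and 15.3-fold lower. Among other granule genes, lactoferrin (Ltf) was at log2 4.80 in KSL and 0.06 in MP and Camp at 2.46 and -0.62, whereas the collagenase gene Mmp8, chosen after its values were seen, ran the other way, at -2.64 and 0.80. Of 19 measured members 8 were at least 2-fold higher and 7 lower in KSL, where the median of 0.42 stood at the 99.3 percentile of random lists. It turned to -0.03 with the 75th percentile over all probes and to -0.32 with spike-in scaling. Both shift all genes of an array alike, and the percentile stayed at 99.3 with each. In MP cells 2 of 20 were higher and 10 lower, with a median of -0.97, below all 10000 random lists, while monocyte and macrophage genes had an MP median of 1.62 and tissue macrophage genes of 4.63. With limma 7 of 19 passed over all probes, 6 lower and 1 higher, so that the calls and the KSL median differ in sign, and 8 passed adjusted over the list alone.

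Stem cell genes were higher with Plzf in both populations, with median log2 changes of 1.45 in KSL and 1.57 in MP against 0.27 and 0.02 for random lists, and as low as 0.71 with spike-in scaling in KSL and 0.91 with normexp in MP. At least 2-fold higher were 10 of 13 measured members in KSL, with 0 lower, and 10 of 13 in MP, with 1 lower (Hlf, at -1.11). Gata2, a transcription factor of stem cells and mast cells, was 5.95-fold and 7.54-fold higher, Ly6a, which encodes Sca-1 and is itself inducible by interferon, 4.99-fold and 6.36-fold, Procr 5.78-fold and 2.68-fold, and the homeobox gene Meis1 2.96-fold and 3.84-fold. These 4 of 13 passed limma over all probes, and 9 passed adjusted over the list alone. The list shares members with other lineages: of its 24 members with a probe 5 are in another list, among them Gata2 with mast cell genes and, picked after their values were seen, Vwf (log2 at least 1.13 in KSL and 1.72 in MP) and Mpl (1.67 in MP) with megakaryocyte genes. Medians of other lineages moved with it, at 1.65 and 1.71 for megakaryocyte and 2.66 and 2.25 for erythroid genes. Hox and self-renewal genes, with Meis1 among them, had medians of -0.01 in KSL and -0.04 in MP, at the 12.3 and 42.3 percentiles. Their sign turned with normexp and over members well above background on all 4 arrays in KSL, and with normexp and spike-in scaling in MP. In KSL the list fell below the central range of random lists with quantile normalisation, at -0.62 and the 0.04 percentile. It did so too with the deposited values (-0.62, at 0.06) and the mean over probes (-0.28, at 0.5). The KSL percentile was 9.68 with normexp and 38.98 over members well above background on all 4 arrays. With spike-in scaling and median centring it stayed at 12.3. Of 13 members 1 was higher and 2 were lower in KSL, and 2 and 3 in MP. Flt3, the receptor for FLT3 ligand, was 2.20-fold and 5.13-fold lower, and Myb 1.84-fold and 5.33-fold lower. Of these 13 members 1 (Meis1, higher) passed limma over all probes, and 5 adjusted over the list alone. Among genes of the Eya-Six-Dach network 3 of 5 measured members were higher in KSL (median 1.59, or 0.85 with spike-in scaling), and 2 of 6 were higher and 1 lower in MP, where the median was -0.16, at the 27.2 percentile, and the mean 0.26. The KSL median was the value of Six5, at dim signals of 23.3 with GFP and 44.7 with Plzf. Eya1 stood at 0.31 and Eya3 at 0.25 in KSL. Eya2 was the 1 member that passed limma, over all probes and adjusted over the list alone.

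Those genes of the erythroid and megakaryocyte lineages that could be measured were mostly higher. Of 14 erythroid genes with a probe 5 were measured in KSL and 9 in MP, and of the 9 only 5 were well above background with GFP, so that 4 are bounds. Of 7 red cell genes outside the globins, picked after the data were seen, 1 was well above background on any array, and globin and haem genes, also chosen then, had medians of -0.10 and -0.34. Erythroid genes had medians of 2.66 in KSL, with 4 of 5 measured members at least 2-fold higher, and 2.25 in MP, with 7 of 9 higher and 0 lower in both; with normexp the medians were 1.61 and 1.13. Beside Hbb-bt they included carbonic anhydrase Car2 (6.32-fold and 4.74-fold) and Ermap (2.58-fold and 2.46-fold). Of 5 erythroid members 3 passed limma over all probes, all higher, and 4 adjusted over the list alone. Megakaryocyte genes had medians of 1.65 and 1.71, with 5 of 7 higher in KSL and 10 of 12 in MP, 0 lower in both, and platelet factor Pf4 was 8.22-fold and 6.75-fold higher. Over members well above background on all 4 arrays the megakaryocyte medians were 0.37, at the 83.2 percentile, and 0.63, at the 90.2 percentile, within the range of random lists. Those members were only Pf4, Itgb3 and Fli1, too few for their place among random lists to decide. Of 11 members tested 6 passed limma over all probes, all higher, and 8 adjusted over the list alone.

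Genes of monocytes and macrophages were higher, more so in MP cells, though that difference was not tested. In MP 9 of 16 measured members were at least 2-fold higher and 0 lower, with a median of 1.62, above all random lists, or 0.76 over members well above background on all 4 arrays. In KSL 4 of 14 were higher and 1 lower, with a median of 0.74, which fell below 0 with spike-in scaling but stayed at the 99.99 percentile of random lists. Adgre1, which encodes the macrophage antigen F4/80, was 3.90-fold higher in KSL and 9.46-fold in MP, the lysosomal gene Cd68 2.11-fold and 6.43-fold, and Cd14, a coreceptor for endotoxin, 1.80-fold and 9.36-fold. With limma 3 of 15 passed over all probes, all higher, and 6 adjusted over the list alone. Tissue macrophage genes, named after the data were seen, moved with this list. Mast cell, basophil and eosinophil genes split: the basophil protease Mcpt8 was 12.6-fold and 4.29-fold lower and the eosinophil granule gene Prg2 9.22-fold and 3.34-fold higher. Of 7 measured members 4 were higher and 1 lower in KSL (median 1.78, or 1.04 with spike-in scaling), and of 12 in MP 4 were higher and 4 lower. The MP median of -0.81, with a mean of -0.14, became 1.21 over the members well above background on all 4 arrays. Of 9 members tested 4 passed limma over all probes, 3 of them higher, and 7 adjusted over the list alone.

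Lymphoid genes had no direction that held, with medians of 0.32 in KSL, at the 47.0 percentile and below 0 with spike-in scaling and with the 75th percentile over all probes, and 0.38 in MP, at the 74.6 percentile. Over members well above background on all 4 arrays these were -0.07 and -0.35. Of 12 measured members 4 were higher and 3 lower in KSL, and of 8 in MP 2 were higher and 2 lower. Cd79b, a part of the B cell receptor, was 2.38-fold and 3.94-fold lower. With limma 2 of 9 passed over all probes, both higher, and 3 adjusted over the list alone. Innate T cell genes, the cells in which Plzf normally acts among lymphocytes, had medians of 1.08 and 1.27, with 6 of 12 higher and 2 lower in KSL and 5 of 9 higher and 1 lower in MP. Over members well above background on all 4 arrays the innate T cell medians were 0.25, at the 69.3 percentile, and 0.78, at the 92.3 percentile, within the range of random lists. Those members were only Id2, Il18rap and Cd44, too few for their place among random lists to decide. With normexp the MP median of innate T cell genes fell to 0.44, at the 96.4 percentile and within that range as well. Id2, an inhibitor of E proteins, was 9.53-fold and 3.16-fold higher. Of 8 members tested 4 passed limma over all probes, 3 of them higher, and 6 adjusted over the list alone.

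DNA replication and mitosis genes were lower in MP cells with Plzf. Of 15 measured DNA replication genes 12 were at least 2-fold lower in MP and 0 in KSL, with medians of -1.50 and -0.44, below all random lists in MP and at the 0.05 percentile in KSL. Mcm5, a subunit of the replicative helicase, was 4.50-fold lower in MP and 1.26-fold lower in KSL, and Rrm2, a subunit of ribonucleotide reductase, 4.33-fold and 1.80-fold lower. Of 15 mitosis genes 10 were lower in MP (median -1.25) and 0 in KSL (median -0.22, at the 5.19 percentile, with 1 higher, Mki67). The mitotic kinase gene Plk1 was 3.44-fold lower in MP and 1.52-fold in KSL, and Aurka 2.92-fold and 1.62-fold. With limma 0 of 15 DNA replication genes passed over all probes and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05, and for mitosis genes it was 0, 0 and 3. Both lists kept their sign in both populations under every scaling tried, and with spike-in scaling the KSL medians were -1.18 and -0.96. On the same MP arrays monocyte and macrophage genes had a median of 1.62 and tissue macrophage genes, chosen after the data were seen, of 4.63, with 12 of 15 higher (1.28 over members well above background on all 4 arrays).

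Among cyclin D and CDK inhibitor genes 3 of 9 measured members were higher and 0 lower in KSL, where the median of 0.37, at the 85.4 percentile, fell below 0 with spike-in scaling and the 75th percentile over all probes, and 2 were higher and 1 lower in MP (median 0.38, at the 84.3 percentile, or -0.37 over members well above background on all 4 arrays). Ccnd1, which encodes cyclin D1, was 2.32-fold and 6.40-fold higher. With limma 1 of 8 passed over all probes and 2 adjusted over the list alone. Myc target genes had medians of -0.34 in KSL, at the 0.60 percentile, and -0.44 in MP, at the 15.8 percentile, with 0 of 13 at least 2-fold apart in either, and spike-in scaling put the KSL median at -1.09. With limma 0 passed over all probes, 0 adjusted over the list alone and 0 were at an unadjusted p under 0.05. Among p53 target and apoptosis genes 2 of 15 were higher in KSL (median 0.22, at the 70.7 percentile, below 0 with spike-in scaling and the 75th percentile over all probes) and 7 of 15 in MP (median 0.63, at the 98.7 percentile, or 0.28 with the last of these), 0 lower in both. Bcl2l11, which encodes the cell death protein Bim, was 1.04-fold higher in KSL and 5.04-fold in MP. With limma 0 of 15 passed over all probes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05.

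Immediate early genes had medians of 0.69 in KSL, at the 98.4 percentile and below 0 with spike-in scaling, and 1.28 in MP, at the 99.9 percentile, or 0.78 with normexp, with 3 of 9 and 6 of 11 measured members higher and 0 lower. The phosphatase gene Dusp1 was 9.61-fold and 11.7-fold higher and Atf3 1.93-fold and 14.2-fold. With limma 1 of 10 passed over all probes (Dusp1) and 6 adjusted over the list alone. Cytokine signalling target genes had medians of 0.58, at the 96.9 percentile and below 0 with spike-in scaling, and 0.92, at the 99.4 percentile, or 0.55 with normexp, with 4 of 11 and 6 of 12 higher and 0 lower. Socs1, a feedback inhibitor of JAK kinases, was 3.0-fold and 9.23-fold higher. With limma 3 of 11 passed over all probes and 4 adjusted over the list alone.

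Chromatin regulator genes had a KSL median of 0.10, at the 24.8 percentile and below 0 with every other scaling except normexp, and an MP median of -0.31, from -0.66 to -0.16 over the alternatives. Of 19 measured members 2 were higher and 2 lower in KSL, and 1 higher and 3 lower in MP. Dnmt3l, a cofactor of DNA methyltransferases, was 7.10-fold and 10.4-fold lower and was the 1 of 19 that passed limma over all probes and the 1 adjusted over the list alone. BTB zinc finger genes, the family of Plzf, had medians of 0.46 in KSL, at the 74.7 percentile and below 0 with spike-in scaling, and 0.84 in MP, at the 94.7 percentile, or 0.33 with normexp. In KSL 2 of 8 were higher and 1 lower, and in MP 3 of 9 and 1. Bcl6 was 2.51-fold and 2.16-fold higher and Patz1 2.04-fold and 6.30-fold lower. Of 8 members tested 1 passed limma over all probes and 3 adjusted over the list alone. Stromal and endothelial genes, of which 4 were measured, had medians of 0.26 in KSL, below 0 with spike-in scaling, quantile normalisation, the deposited values and the 75th percentile over all probes, and 0.32 in MP, just below 0 with the last of these. In KSL 0 were at least 2-fold apart and in MP 1 was higher. Reference genes had medians of 0.01 in KSL, below 0 with the mean over the probes of a gene, normexp and 3 other scalings, and -0.17 in MP. Of 12 members 0 were at least 2-fold apart in KSL and 1 was higher in MP, the MHC class I light chain gene B2m (3.32-fold). Of stromal and endothelial genes 0 of 4 passed limma over all probes, 0 adjusted over the list alone and 0 were at an unadjusted p under 0.05. Of reference genes it was 0 and 0 of 12, with 1 at an unadjusted p under 0.05.

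**Figure D3:**
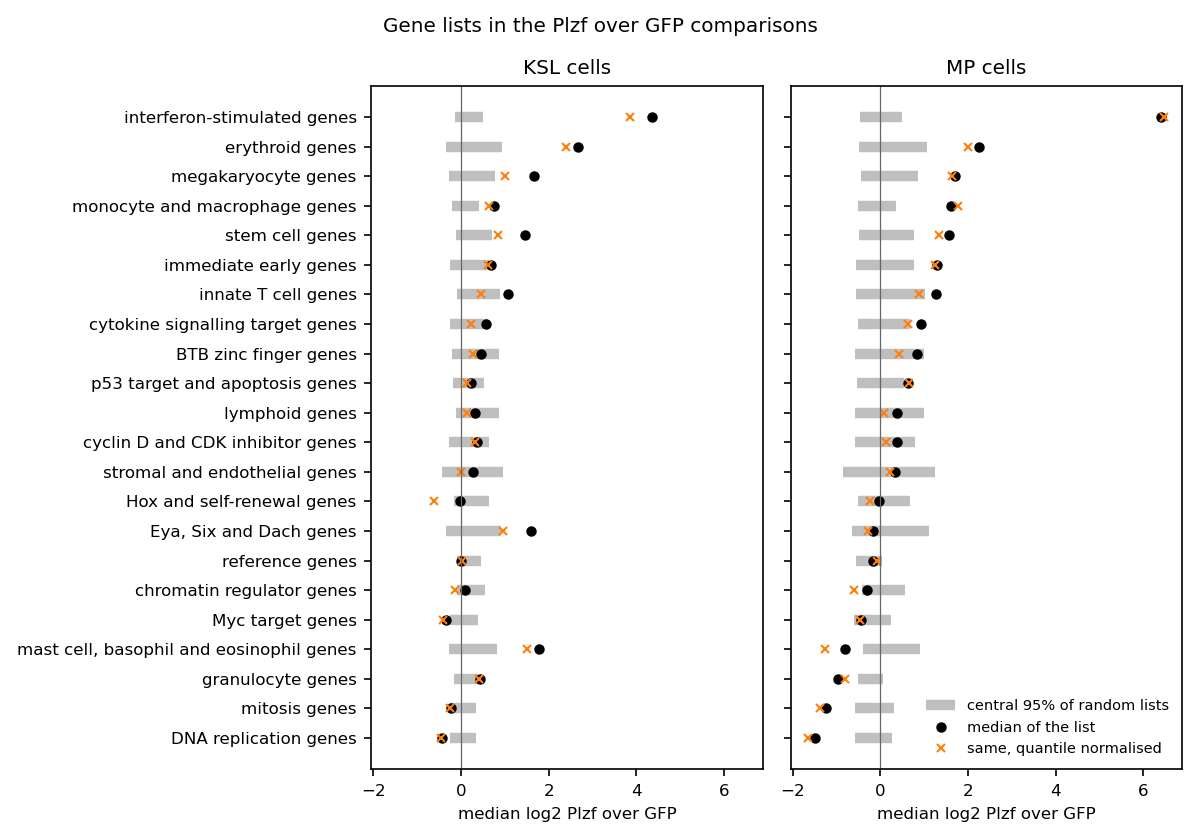
Median log2 ratio of Plzf to GFP for the 22 gene lists in KSL cells (left) and MP cells (right), 1 array per group: black points with the 75th percentile scaling, orange crosses with quantile normalisation, grey bars the central 95% of 10000 random lists matched on level. Interferon-stimulated genes lie at 4.37 and 6.41, and DNA replication genes at -0.44 and -1.50; the KSL medians of granulocyte, lymphoid, reference and several other lists turn sign under other scalings named in the text.

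Some genes differed between the populations in their response. Larger in MP than in KSL was the difference for the channel gene Mcoln2 (log2 4.84 in MP and -0.36 in KSL), Mndal, Tmem171, the B cell adaptor gene Blnk and the high-affinity IgG receptor gene Fcgr1 (4.63 and -0.07). Larger in KSL was that for the purinergic receptor gene P2rx5 (4.82 in KSL and -1.06 in MP) and the stefin genes Stfa1 (7.15 and 1.61), Cstdc5, Stfa2l1 and Cstdc4. At least 2-fold apart in opposite directions were 91 of 19032 probes, 59 higher in KSL and lower in MP and 32 the reverse, where independent lists would give 255 and 72.4. With quantile normalisation it was 42 and 53, and with spike-in scaling 13 and 182. With 1 array per group no difference between the populations was tested.

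The arrays with GFP alone described the populations themselves. Higher in MP were genes of neutrophil granules, with Ltf 3726-fold, Ngp 1536-fold and Camp 883-fold higher, the ficolin gene Fcnb (262-fold), the stefin genes Stfa2l1, Stfa2, Stfa3, Cstdc4 and Cstdc5 (98.4-fold to 155-fold) and Prg2 (104-fold). Higher in KSL were Epb41l4b (28.0-fold), the actin-severing gene Scin (23.1-fold), the myosin light chain gene Myl4 (20.5-fold), Cox6a2 (16.6-fold) and Ly6d, a marker of early lymphoid progenitors (16.2-fold), then Timp1, Chn2, Slc30a4, Rcor2 and Ptprcap. In all, 7279 of 20723 probes were at least 2-fold apart, 5115 higher and 2164 lower in MP, but with quantile normalisation 2880 were higher and 3107 lower, and with spike-in scaling 1225 and 8572.

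By list, granulocyte genes were higher in MP (15 of 19 measured members, median log2 3.38), as were megakaryocyte genes (10 of 11, median 3.69), mast cell, basophil and eosinophil genes (10 of 12, median 1.81), monocyte and macrophage genes (8 of 15 with 1 lower, median 1.31), immediate early genes (6 of 10, median 1.32) and interferon-stimulated genes (9 of 14 with 1 lower, median 1.27). With spike-in scaling the medians of the last 3 were 0.24, 0.25 and 0.20 and that of mast cell, basophil and eosinophil genes 0.74, and with normexp that of megakaryocyte genes was 1.92. Myc target genes were lower in MP, with 12 of 13 at least 2-fold lower and a median of -2.07, below all random lists. The nucleolar gene Gnl3 was 7.69-fold lower and Odc1, the first enzyme of polyamine synthesis, 5.32-fold lower. Hox and self-renewal genes had a median of -0.75, or -0.03 with normexp, with 5 of 13 lower and 1 higher, and Hoxa7 was 9.07-fold and Meis1 6.00-fold lower. Lymphoid genes had a median of -0.68, which was 0.00 with normexp, with 3 of 9 lower and 0 higher, and the T cell kinase gene Lck was 6.32-fold lower. Stem cell genes had a median of -0.15, at the 8.51 percentile, which rose above 0 with normexp, with 3 of 12 higher and 3 lower. Cd34 was 9.07-fold lower and Hlf 4.18-fold higher, the latter at dim signals of 26.54 on KSL GFP and 58.31 on MP GFP before scaling. Erythroid genes had a median of -0.66, at the 3.85 percentile, and a mean of 0.28 over 5 members, with -0.08 as the median under normexp, 2 of them higher and 1 lower.

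Of 22 lists, 6 lay above and 3 below the central 95% of random lists in this comparison. With normexp the Hox and self-renewal list, at the 2.65 percentile, and the lymphoid list, at 5.555, fell back within it. Over members well above background on all 4 arrays the lymphoid list, at 7.87, and the immediate early list, at 97.44, did so. With the 75th percentile scaling stem cell and erythroid genes lay within the central 95%, and so did the lists that follow. DNA replication genes had a median of -0.33 (2 of 15 lower), mitosis genes -0.26 (1 of 15 higher), innate T cell genes 0.00 (1 of 7 higher, from -0.89 to 0.84 over the alternatives) and reference genes -0.09 (1 of 12 higher, Actb at 2.02-fold, which spike-in scaling turned to a log2 change of -0.05). Genes of the Eya-Six-Dach network had a median of 0.82 (3 of 6 higher), cyclin D and CDK inhibitor genes 0.76 (3 of 7 higher and 2 lower) and BTB zinc finger genes 0.84 (3 of 7 higher and 1 lower), all below 0 with spike-in scaling. Medians were 0.21 for p53 target and apoptosis genes (5 of 15 higher and 3 lower), 0.22 for cytokine signalling target genes (3 of 10 higher and 1 lower), 0.40 for chromatin regulator genes (5 of 19 higher and 2 lower) and 0.25 for stromal and endothelial genes (0 of 5 apart), and each of these was below 0 with at least spike-in scaling and the 75th percentile over all probes. With Plzf on both arrays, 8357 of 21898 probes were at least 2-fold apart between MP and KSL, 5076 higher and 3281 lower in MP, and 3925 and 4281 with quantile normalisation.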

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

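All tests in this part were chosen after the results were seen. Among the named genes, 4 were at least 2-fold apart in opposite directions in the KSL and MP comparisons of Plzf with GFP, and none of these differences between populations was tested. Blnk, an adaptor of B cell receptor signalling, stood at a log2 change of -1.75 in KSL and 3.02 in MP. P2rx5 stood at 4.82 in KSL and -1.06 in MP. Ngp, a protein of neutrophil granules, stood at 2.16 in KSL and -1.47 in MP. Hlf, a transcription factor of stem cells, stood at 1.45 in KSL and -1.11 in MP. Its signals were dim, at 26.54 and 46.24 on KSL GFP and Plzf and 58.31 and 26.65 on MP GFP and Plzf.

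Interferon-stimulated genes were higher in both Plzf arrays, and the lowest list median over all scalings and both populations was still 3.03, which argues against the choice of scaling as the cause. Macrophages of 1 kind in both sorted samples would bring their transcripts in 1 ratio, but the test did not decide. It took genes dim on KSL GFP and well above background on MP Plzf. Of these, 11 tissue macrophage genes differed from KSL Plzf to MP Plzf by a median log2 of 5.67 (bounds where KSL Plzf was dim). For 8 interferon-stimulated genes it was 3.60, a gap of 2.07 with a bootstrap 95% interval over genes from -1.21 to 2.98 (label: cannot tell). All 19 interferon-stimulated genes were well above background on MP Plzf, so that filter removed only macrophage genes and can raise the gap. A first version applied the KSL GFP filter to the macrophage list alone and gave a gap of 2.79. This was over its bound of 1 and so against macrophages as the source. Test, prediction and label rule were rewritten after that outcome, which turned the verdict from against to open. Of the 18 tissue macrophage genes 4 were well above background on KSL GFP, 12 on KSL Plzf, 8 on MP GFP and 15 on MP Plzf, with Apoe brightest on both Plzf arrays (1708 and 104314) and Cd5l next on MP Plzf (19553, against 21.8 on KSL Plzf), and 1 is in another list; the sort for GFP should remove cells without the vector, but not macrophages that carried it, so macrophages stay open. An answer to the virus preparation or to a foreign insert, apart from the function of Plzf, may also be the source: Ifnb1 was higher by a log2 change of at least 1.38 in KSL and 3.03 in MP, and without a control insert this cannot be told apart from Plzf itself, which the design names and which stays open and untested.

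The Zbtb16 probe was not well above background on any array although Plzf was transferred. A candidate explanation is that the probe lies outside the coding sequence, which a cDNA vector carries: 2 of the 3 forward frames of the 60-base probe hold a stop codon, and 1 is open. The bound first set for this test, exactly 1 open frame, would have counted against that explanation, but it was wrong, since 87.4% of 10000 shuffles of the same bases had stop codons in as few frames. A coding probe and a noncoding probe thus cannot be told apart by this test, and a low level of the transferred transcript or a mislabelled array stays open as well.

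Beta-like globin genes were higher in both Plzf arrays. Erythroid cells in the KSL Plzf sample, of the makeup that the MP Plzf array would show, would need an Hba-a1 signal of 293, against 3.91 seen. This argues only against cells of that makeup. The 293 assumes that Hba-a1 and Hbb-bt on MP Plzf came from erythroid cells, which is itself undecided. Erythroid cells of another makeup in KSL Plzf therefore stay open. Reading of 1 beta globin transcript by all 4 beta-like probes would give them 1 ratio between MP Plzf and KSL Plzf, but log2 ratios ran from 0.61 for Hbb-bt through 0.79 for Hbb-b2 and 1.16 for Hbb-y to 2.78 for Hbb-bh1, a span of 2.17 against a bound of 1. That span rests on Hbb-bh1, so it speaks against cross-hybridisation of this kind for that probe only. Hbb-bt, Hbb-b2 and Hbb-y lay within the bound of each other, which leaves 1 shared transcript open for them. Erythroid cells in the MP Plzf sample cannot be told apart from expression in the transduced cells, since 1 of 7 red cell genes outside the globins was well above background there, and the sort for GFP leaves in those that carry the vector. A direct action of Plzf on these genes was not tested.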

How the results depend on the processing

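The spike-in scaling and the 75th percentile over all probes were chosen after seeing the data; the other alternatives were fixed before. The cause was not tested for any change given here, except that counts under another fold threshold, filter or number of probes follow from how those are built. With spike-in scaling 5114 probes were at least 2-fold apart in KSL and 195 in opposite directions, and limma called 732. With normexp the counts were 1596 in KSL, 2989 in MP, 4791 for MP over KSL with Plzf, 785 in both and 22 in opposite directions. Limma, with 1200 calls at the start, called 0 with quantile normalisation, 0 with the deposited values, 499 with median centring, 225 with the 75th percentile over all probes, 782 with 1 probe per gene, 533 with the mean over probes and 1901 at an adjusted p of 0.1. With a trend it called 1727, with a robust trend 1406, and 1200 that were also at least 2-fold. Total counts not given here stayed within 1.5 times of those reported, and r within 0.1, but the split into higher and lower moved by more: with the 75th percentile over all probes it was 1442 and 1651 in KSL, 2780 and 4058 in MP and 788 and 857 in both, and with median centring 2028 and 845 in KSL. Without a filter on dim probes the counts were 9859 in KSL, 12027 in MP, 15137 for MP over KSL with GFP, 14504 with Plzf, 3377 in both and 693 in opposite directions, with r at 0.381 and 3013 limma calls. With only probes well above background on all arrays compared they were 2223 in KSL and 1100 in both. At 1.5-fold they were 7202, 10850, 11715, 13519, 3668 and 495, and at 3-fold 1362, 2920, 3123, 4066, 704 and 11, in the order KSL, MP, MP over KSL with GFP, the same with Plzf, both, and opposite. Among list medians outside the central 95% of random lists and gene values at least 2-fold, directions turned for the KSL medians of granulocyte genes (-0.32 with spike-in scaling, -0.026 with the 75th percentile over all probes), monocyte and macrophage genes (-0.0023 with spike-in scaling) and immediate early genes (-0.054 with spike-in scaling), for the MP median of mast cell, basophil and eosinophil genes (1.21 over members well above background on all 4 arrays) and for Actb between the GFP arrays (-0.046 with spike-in scaling). Of 230 values of named genes at least 2-fold that was the 1 that turned, and of all 353, 69 turned under at least 1 alternative. Where the KSL medians of granulocyte, monocyte and macrophage, and immediate early genes turned, their percentiles among random lists did not move. Over all 22 fixed lists, 10 medians in KSL, 20 in MP and 12 for MP over KSL with GFP kept their sign under all 6 other scalings; spike-in scaling turned 11 in KSL, the 75th percentile over all probes 7, and quantile normalisation 2. Counting only members well above background on all 4 arrays turned 2 of 20 in KSL and 3 in MP. Of 419 gene and list values, 369 moved by more than their tolerance with the 75th percentile over all probes, 290 with spike-in scaling (4 more reversed), 251 with median centring, 237 with the deposited values, 231 with quantile normalisation, 202 with normexp and 54 with the mean over probes. The tolerance was technical spread for gene values and was set by the range of the random lists for list medians. Leaving out an array was not possible, since each group has 1 and limma would keep no residual degree of freedom. With population as a term the limma fit already pairs Plzf with GFP within each population. Each population has 1 array per virus, so no further paired analysis was possible. All arrays share 1 slide. Signal over background limits the rest: from 34.2% to 36.2% of probes were well above background on an array, and changes elsewhere are bounds or unseen.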

Other observations

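All lists and tests in this part were chosen after the data were seen. The list called stefin and neutrophil granule genes had 8 of 13 measured members higher and 2 lower with Plzf in KSL (median log2 6.67, mean 4.23). In MP 11 of 14 were higher and 2 lower (median 1.79, mean 2.05). It shares no member with the granulocyte genes above. Its medians therefore do not speak for Ctsg, Elane, Prtn3, Ltf, Camp, Ngp or Mmp8. Il1b, which encodes interleukin 1 beta, stood at 6.67 in KSL and 4.70 in MP, so the KSL median of the list is at its value. Stefin genes stood above Il1b in KSL, from 7.15 for Stfa1 to 9.01 for Stfa2. They are close paralogs whose transcripts a probe can share. The KSL median therefore does not show that the neutrophil granule genes of the list were higher. With limma 7 of 14 passed over all probes, 6 of them higher and 1 lower. Inflammatory cytokine and chemokine genes were higher in 8 of 12 in KSL (median 2.33) and 14 of 16 in MP (median 2.98), with 0 lower, and the KSL median was 1.44 with normexp. The monocyte attractant genes Ccl2 (2.40 and 6.89) and Ccl4 (2.33 and 6.31) were among them. With limma 8 of 12 passed. Guanylate-binding and immunity-related GTPase genes, which interferon induces, were higher in 9 of 11 in KSL (median 2.28) and 15 of 16 in MP (median 3.38, or 1.96 with normexp), with 0 lower, and 9 of 12 passed limma. Of 13 interferon genes with a probe, 11 were well above background on no array and 2, Ifnb1 and Ifnl3, on at least 1.

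Tissue macrophage genes were higher in 6 of 12 measured members in KSL (median 1.53, 0 lower) and 12 of 15 in MP (median 4.63, 1 lower, Vcam1 at -3.68), and 6 of 12 passed limma. Over members well above background on all 4 arrays the medians were 0.83 and 1.28. The complement genes C1qb and C1qc stood at 5.82 and 6.90 in MP. Antigen presentation genes had medians of 0.88 in KSL (7 of 18 higher, 0.14 with spike-in scaling) and 1.17 in MP (10 of 17 higher), with 0 lower. Of MHC class II genes, picked after their values were seen, H2-Ab1 stood at 3.23 in KSL and -0.97 in MP, H2-Aa at 4.01 and -0.25 and the invariant chain gene Cd74 at 4.33 and 0.70. The difference between populations was not tested. With limma 0 of 17 antigen presentation genes passed over all probes, with 10 at an unadjusted p under 0.05. Globin and haem genes split, with 4 of 12 higher and 1 lower in KSL and 6 of 14 higher and 1 lower in MP. Their medians were -0.10 and -0.34 and their means 1.34 and 1.73, so median and mean differ in sign. Alas1, the enzyme of the first step of haem synthesis outside red cells, stood at -1.38 and -2.26, and with limma 5 of 12 passed, 4 of them higher. With GFP alone, medians for MP over KSL were 3.71 for stefin and neutrophil granule, 2.70 for tissue macrophage, 1.38 for antigen presentation, 1.21 for cytokine and chemokine, -0.32 for globin and haem and 0.04 for guanylate-binding and immunity-related GTPase genes, the last of which was below 0 with all scalings but normexp. With spike-in scaling those of antigen presentation and of cytokine and chemokine genes were 0.32 and 0.15, and with normexp that of tissue macrophage genes was 1.55.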
